A study of Rattus norvegicus with 2 samples.

How the data were processed

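Messenger RNA was measured in cortical neurons from rat embryos (E18), in 1 siNC library and 1 siYthdf3 library, grouped by the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, 1 ug went into a digital mRNA library kit that tags each cDNA molecule with a unique molecular identifier of 12 random bases, and libraries were sequenced as paired reads of 150 bases on an MGI instrument. The submitters' processing notes name fastp 0.23.2, STAR 2.7.6a, featureCounts, Subread 1.5.1, edgeR 3.40.2 and StringTie 2.1.4, without roles or order. Whether reads were collapsed by identifier, whether counting used strand, the genome build and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes are therefore uncertain.

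The authors deposited a table of FPKM values, which scale reads by gene length and by the library's total, per gene and library, with Ensembl gene identifiers, symbols, coordinates and gene lengths, per the file headers. FPKM times length was a whole multiple of 1 step per library for 100% of values, within 0.05 of a whole read, which gives 15392218 assigned reads in siNC and 22586543 in siYthdf3. A row at 0 has an upper limit of 3 reads, or 0.195 FPKM in siNC and 0.133 FPKM in siYthdf3 for a gene of 1 kilobase. The recovered reads served to set counting intervals and depth, and no count test was run on them.

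The measure was log2 of the siYthdf3 over the siNC value after adding a pseudocount of 0.5 FPKM, which understates the differences of low genes. Genes with a mean of at least 1 FPKM over both libraries entered, 13172 of 21224. A rule of size of 2-fold was used, since 1 library per group allows no test between conditions. Counting intervals of the FPKM ratio are exact Clopper-Pearson 95% intervals of the share of a gene's reads that fell in siYthdf3, converted to a ratio. They cover counting error only and not differences between samples, and they are too narrow where reads are copies of 1 molecule. For abundant genes they can exclude 1 at small differences. Interval counts of lists are on the FPKM scale only. The share of all genes whose interval excludes 1 is not given beside them. Lists between the percentile limits also held many such intervals, so these counts alone do not set a list apart. Genes 2-fold apart from counting error alone were counted in 100 simulated pairs of libraries with equal expression.

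Before the data were examined, 40 gene lists were fixed, 29 of processes and 11 of cell types, and 816 of their 854 entries matched a symbol in the table. Not found were, among others, Gapdh, Ldha, Pkm and Tpi1 of the glycolysis list and 6 ribosomal protein genes. For the 194 symbols on more than 1 row the row with the highest mean was used. Each list's median log2 ratio was ranked among 10000 random lists of the same size drawn from 20 bins of mean FPKM, and called apart at percentile 97.5 or above or 2.5 or below. The 3 lists with fewer than 5 measured members are given as values. Over the 37 lists ranked, about 1.85 would lie outside by chance if genes were independent, which genes of a list are not, so a percentile describes these 2 libraries and is no p-value. Gene types came from a RefSeq table of the GRCr8 assembly, matched by symbol for 12090 of the 13172 genes, and none of its coordinates were used.

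Genes named in the text follow a rule fixed before the data were examined. It takes Ythdf3, Wwtr1, Ythdf1, Ythdf2 and Yap1, the 12 highest and 12 lowest log2 ratios at a mean of at least 5 FPKM without placeholder symbols, and from each list up to 4 members with the largest differences plus any member 2-fold apart. Genes said to be chosen after their values were seen fall outside it. Some genes that the rule takes are not reported here.

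The procedure was tested on simulated data for siYthdf3 against siNC over 13173 genes. Of 50 genes changed 3-fold, 45 passed the 2-fold rule, of 50 changed 4-fold 46, of 50 changed 6-fold 50 and of 50 changed 1.5-fold 0. Of 12979 unchanged genes, 81 passed. Unchanged lists fell outside the percentiles in 5.75% of draws, and the intervals held the true ratio for 94.9% of unchanged genes. The lists were drawn from independent normal values and the intervals checked on Poisson reads. Both results were therefore near their nominal levels by design. They check the calculation only, and not its behaviour with correlated genes or differences between samples. Alternatives were pseudocounts of 0.1 and 1 FPKM, other filters, TPM, median centring, rescaling without mitochondrial and top 20 genes, protein-coding genes only, a 1.5-fold rule and unmatched random lists. Added after the data were seen were removal of a length trend, thinning of siYthdf3 reads to the siNC depth, a minimum of 20 reads and random lists matched on length. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.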

Results

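The series measured messenger RNA in cortical neurons from rat embryos at day E18 that had received a negative control small interfering RNA (siNC) or a small interfering RNA against Ythdf3 (siYthdf3). Ythdf3 encodes a reader of m6A, a methyl mark on messenger RNA. Each group had 1 library, so no difference described here has a replicate check and no p-value is given. The siNC library held 15392218 reads assigned to genes and the siYthdf3 library 22586543. Of 21224 gene rows, 19568 had reads in siNC and 20310 in siYthdf3. Mitochondrially encoded genes took 2.62% of the reads in siNC and 2.58% in siYthdf3, and the top 20 genes took 7.13% and 7.05%. Intervals are exact 95% intervals of the ratio of FPKM values, siYthdf3 over siNC, and cover counting error only. Coordinates are those of the deposited table, whose genome build is not given in the sources used here.

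The comparison of siYthdf3 with siNC belongs to a study whose title links Ythdf3 to hypoxic-ischemic injury and to Wwtr1. No label names a hypoxic sample. Ythdf3 itself (ENSRNOG00000010084, chromosome 2, 98350588 to 98382545, plus strand) was lower in the library labelled siYthdf3, at 6.93 FPKM against 9.38 FPKM in siNC. The ratio was 0.739 (interval 0.675 to 0.809), from 994 and 917 reads. Its log2 ratio was -0.41, where the quartiles across genes were -0.17 and 0.14. The SD was 0.33, which rows with few reads widen. At least 1.5-fold lower were 520 of 13172 genes, and Ythdf3 was not among them. The difference in the targeted gene was thus smaller than that of many other genes. The paralogous readers differed less. Ythdf1 had a ratio of 0.993 (interval 0.875 to 1.13) and Ythdf2 of 0.939 (interval 0.846 to 1.04), and both intervals include 1.

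Wwtr1 (ENSRNOG00000016617, chromosome 2, 141648108 to 141766968, minus strand) encodes TAZ, a transcriptional coactivator controlled by the Hippo pathway. It was at 2.96 FPKM in siYthdf3 and 6.23 FPKM in siNC, a ratio of 0.475 (interval 0.409 to 0.550), from 310 and 445 reads. On the scale of log2(FPKM + 0.5) the difference was -0.96, short of the 2-fold rule, and it was -1.05 with a pseudocount of 0.1 FPKM. Its paralogue Yap1 was at 13.9 FPKM against 12.8 FPKM, a ratio of 1.09 (interval 1.00 to 1.19). The 24 measured Hippo pathway core genes, Wwtr1 among them, had a median log2 ratio of 0.08 and went both ways, with 8 intervals above 1 and 7 below. Tead2, a DNA-binding partner of YAP and TAZ, was lower at -0.80, and so was Tead3 at -0.46. Frmd6, an upstream Hippo regulator, was higher at 1.08.

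YAP/TAZ target genes were lower as a list. Their median log2 ratio was -0.25 over 22 measured genes, at percentile 0.02 of 10000 random lists matched on mean expression. Counting intervals lay below 1 for 13 members and above 1 for 3. Such intervals are common. The extracellular matrix list, at percentile 35.5, had 9 above 1 and 11 below among 25 genes. The YAP/TAZ targets with the largest differences were Nuak2 at -1.19, Ajuba at -0.89, Birc5 at -0.81 and Igfbp3 at -0.70. Birc5 also stands in the cell cycle list, and 7 of the measured targets stand in another list. In the same library, cell cycle genes had a median of -0.88, radial glia and progenitor markers of -0.30 and pericyte, fibroblast and meningeal markers of -0.22. The classical targets Ccn2 and Ccn1, chosen after their values were seen, were at -0.45 and -0.37.

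Across the 13172 gene rows with a mean of at least 1 FPKM, the libraries were close, with a Pearson r of 0.983 across genes, which are not independent replicates. The median log2 ratio was -0.01 and the quartiles were -0.17 and 0.14. At least 2-fold higher in siYthdf3 were 93 genes, and 118 were at least 2-fold lower. Of these, 56 of the higher and 42 of the lower genes had under 20 reads over both libraries, and counting error alone gave on average 44.0 higher and 47.2 lower genes in 100 simulated pairs. Among genes that are protein coding by symbol, 26 were higher and 69 lower, together 95 where counting error alone gave 1.65. The simulated pairs hold no differences between samples or library preparations. An excess over them therefore does not show an effect of the knockdown.

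The lowest ratio among named genes with a mean of at least 5 FPKM was that of Npvf (chromosome 4, 79712520 to 79716236), the precursor of RFamide-related neuropeptides. It was at 1.30 FPKM in siYthdf3 and 23.7 FPKM in siNC, a ratio of 0.055 (interval 0.032 to 0.089), from 18 and 223 reads. Fstl1 (chromosome 11, 62779783 to 62948677), a secreted glycoprotein, followed at 13.1 FPKM against 71.2 FPKM, a ratio of 0.183 (interval 0.172 to 0.195). Genes of cell division were among those that followed. Nde1, a centrosomal protein needed for progenitor division, was at -1.86, the replication helicase subunit Mcm3 at -1.62, the mitotic regulator Cdca3 at -1.48, the mitotic kinesin Kif2c at -1.31 and the kinetochore protein Spc25 at -1.25. Neurog2, a proneural transcription factor, was at -1.25. The calcium sensor Ncald was at -1.32, the chemokine Pf4 at -1.44 and the matrix protein Fbln2 at -1.25. Snord4a was at -1.88 on 3 and 9 reads.

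At the other end, Slc25a33, a mitochondrial carrier of pyrimidine nucleotides, was at 8.80 FPKM in siYthdf3 and 2.55 FPKM in siNC, a ratio of 3.45 (interval 2.57 to 4.70). Pvalb, a calcium-binding protein, was at 1.47 on the log2 scale, Car3, a carbonic anhydrase, at 1.36, and the collagen IX genes Col9a1 and Col9a3 at 1.36 and 1.34. Pgm5 was at 1.33, Dgki, a diacylglycerol kinase, at 1.12 and the transcription factor Sox12 at 1.06. Among abundant genes, Igfbp5 was at 146 FPKM against 70.1 FPKM and Gfap, the intermediate filament of astrocytes, at 141 FPKM against 68.2 FPKM, with a ratio of 2.07 (interval 1.99 to 2.15). The hyaluronan receptor Cd44 was at 49.0 FPKM against 24.0 FPKM. Mir34a, at 1.74, rested on 32 and 6 reads over 102 bases.

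**Figure D1:**
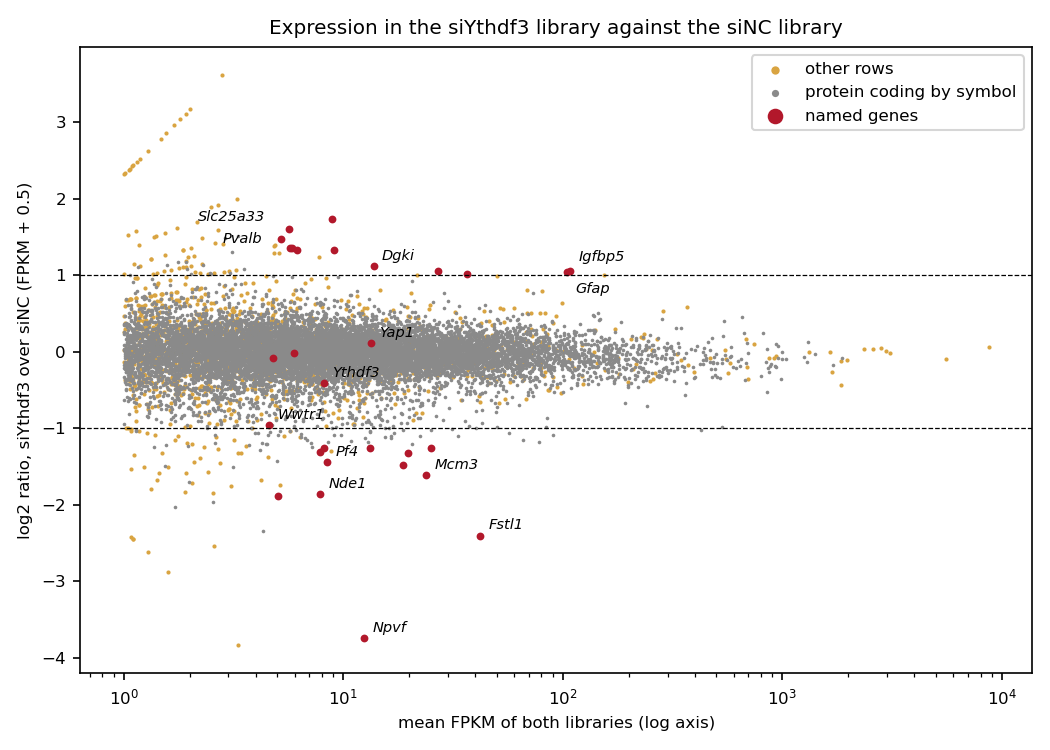
Each point is a gene row with a mean of at least 1 FPKM, with mean FPKM of both libraries on a log axis and the log2 ratio of siYthdf3 over siNC (FPKM + 0.5) on the vertical axis. Dashed lines mark the 2-fold rule, and Npvf and Fstl1 lie lowest among the named genes, at -3.75 and -2.40.

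**Figure D2:**
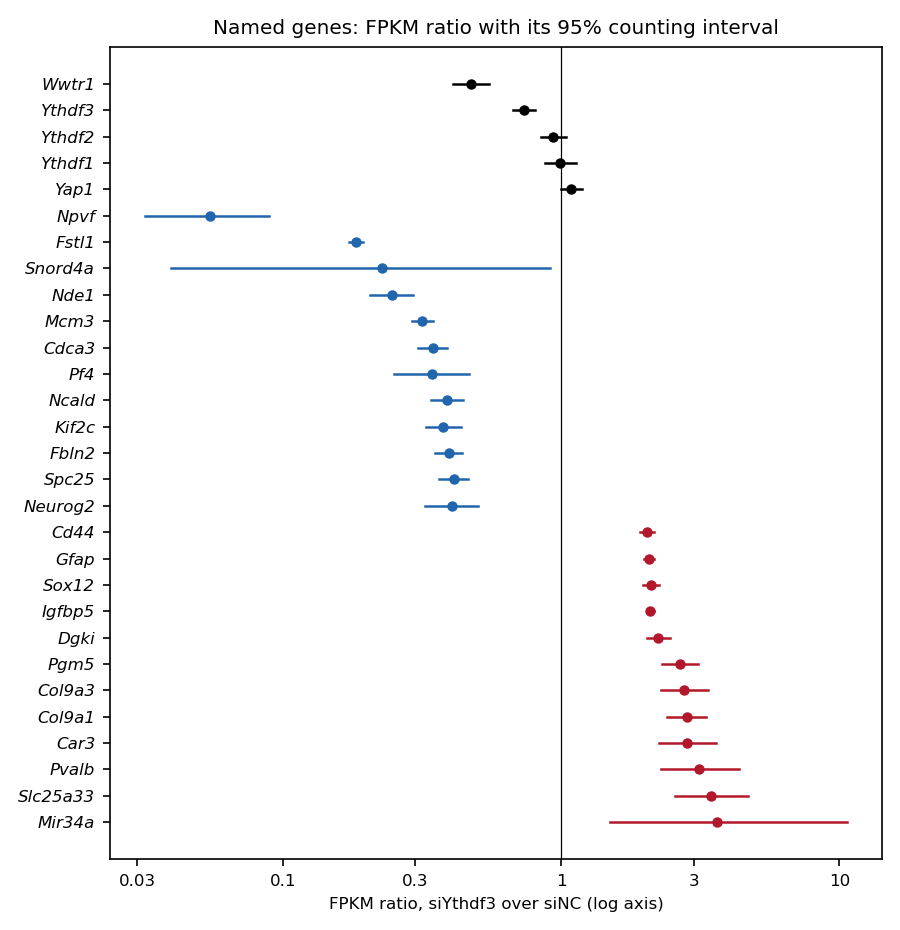
FPKM ratios of siYthdf3 over siNC on a log axis for the 5 genes always named and the 12 lowest and 12 highest log2 ratios, with exact 95% counting intervals as bars. Wwtr1 lies at 0.475 and Ythdf3 at 0.739, and the interval of Yap1 begins at 1.00.

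Cell cycle genes were lower in siYthdf3 as a group. All 25 measured members had an interval below 1, with a median log2 ratio of -0.88 (percentile 0), and 8 were at least 2-fold lower. Top2a, which untangles replicated DNA, was at 40.6 FPKM against 90.8 FPKM, a log2 ratio of -1.15. The mitotic cyclin Ccnb1 was at -1.08 and the kinase Aurka at -1.08. Besides Mcm3, the helicase genes Mcm2, Mcm5 and Mcm6, chosen after their values were seen, were at -0.83, -0.85 and -0.67. Markers of radial glia and neural progenitors were lower too, with a median of -0.30 over 13 genes (percentile 0.05), 8 intervals below 1 and 1 above. Eomes, which marks intermediate progenitors, was at 0.743 FPKM against 4.34 FPKM. The intermediate filament genes Vim and Nes were at 357 FPKM against 708 FPKM and 60.0 FPKM against 110 FPKM, and Notch1 was at -0.53. Fabp7, chosen after its value was seen, was at -0.36.

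Markers of other non-neuronal cells did not all move together. The 9 measured oligodendrocyte lineage markers had a median of -0.35 (percentile 0.17), with 5 intervals below 1 and 1 above. Olig2 was at -0.82, Olig1 at -0.77 and Bcas1 at -0.62, while 2 members were above 0. The 6 measured microglia markers had a median of -0.38 (percentile 0.61), with 3 intervals below 1 and 0 above. Aif1 was at -0.72 and Tyrobp at -1.71 on 8 and 27 reads, while 2 members were above 0, among them P2ry12 at 0.36 with a ratio of 1.45 (interval 0.987 to 2.15). Pericyte, fibroblast and meningeal markers had a median of -0.22 over 9 genes (percentile 2.19), with 6 intervals below 1 and 2 above. Col3a1 was at -0.80 and Myh11 at 0.57. The percentile of this list was 2.57 with a pseudocount of 0.1 FPKM and 2.69 after rescaling to TPM, which also acts as a smaller pseudocount. Both lie outside the limit of 2.5. Astrocyte markers had a median of -0.02 over 12 genes (percentile 49.5), with quartiles of -0.37 and 0.58. Gfap, the glutamate transporter Slc1a2 at 0.80 and Slc4a4 at 0.66 were higher, and the gap junction gene Gja1 at -0.68 was lower.

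**Figure D3:**
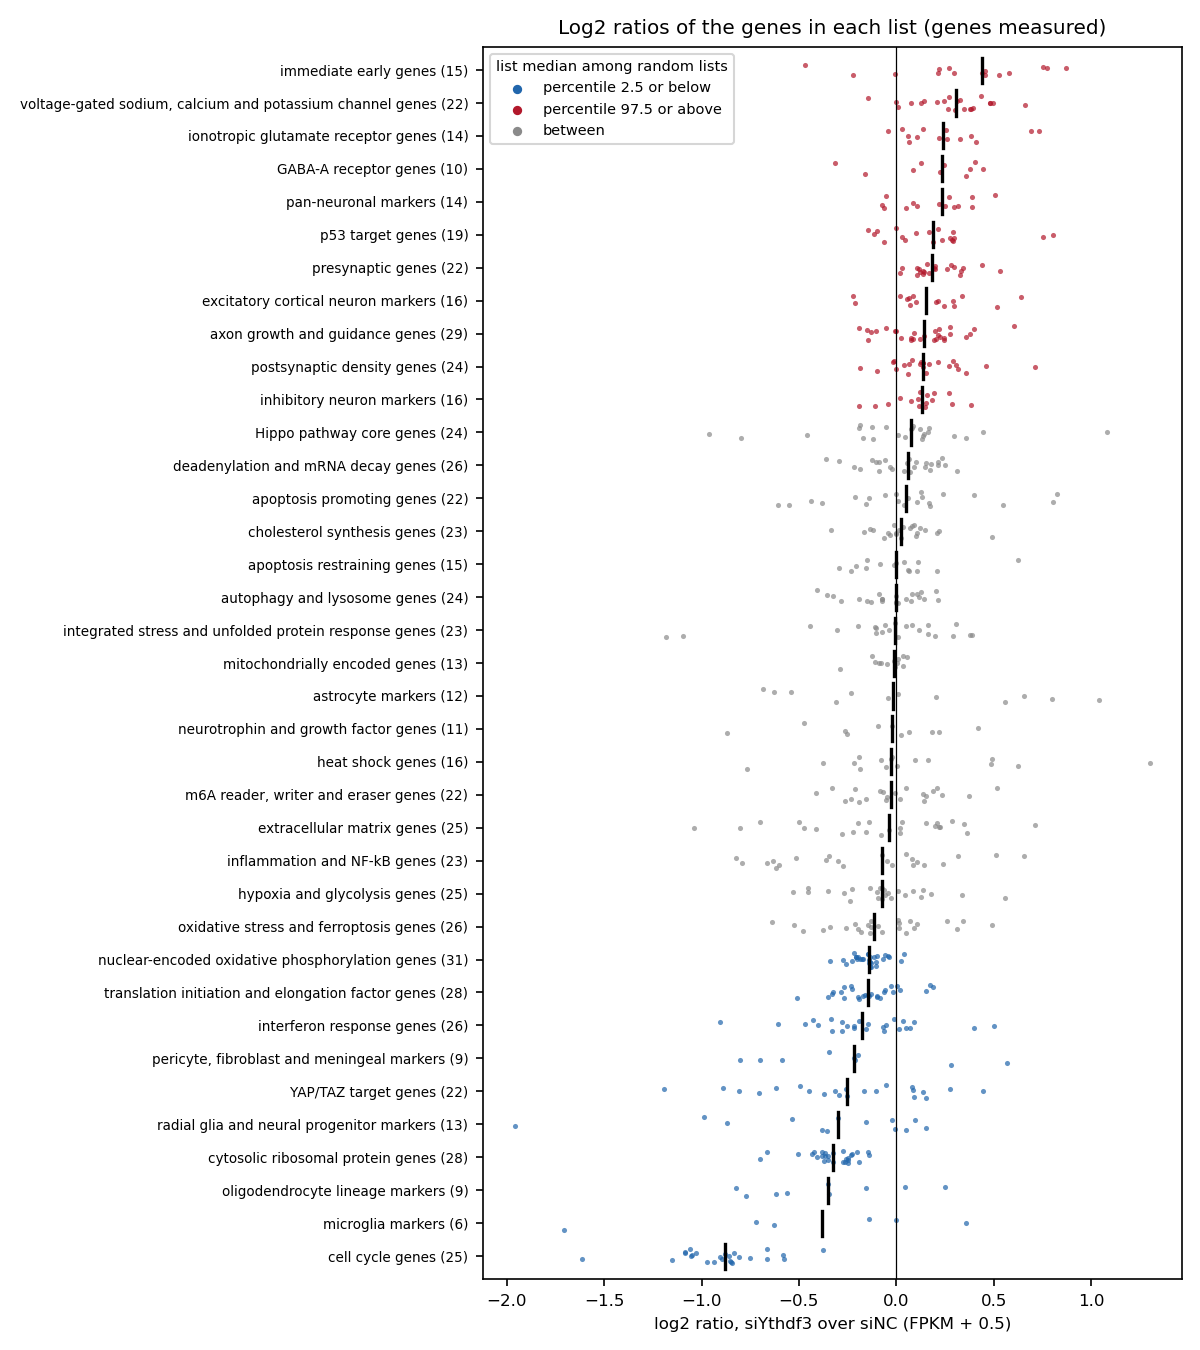
Log2 ratios of siYthdf3 over siNC (horizontal axis) for the measured genes of the 37 lists with at least 5 measured members, 1 list per line with its number of genes, with a bar at each list's median. Colour marks the percentile of that median among random lists matched on mean expression. Cell cycle genes lie lowest with a median of -0.88 and immediate early genes highest with 0.44.

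Neuronal and synaptic genes were modestly higher in siYthdf3. Voltage-gated channel genes had a median log2 ratio of 0.31 over 22 genes (percentile 100), with 17 intervals above 1 and 0 below. The median was 0.19 after a length trend was removed. Sodium channel genes Scn3b and Scn3a were at 0.66 and 0.50. Ionotropic glutamate receptor genes had a median of 0.24 over 14 genes (percentile 99.98), with 9 intervals above 1 and 0 below, led by the NMDA receptor subunits Grin2b at 0.73 and Grin3a at 0.69. GABA-A receptor genes had a median of 0.24 over 10 genes (percentile 99.1), with 5 intervals above 1. Their percentile was 90.9 without the filter on low values, and that of the glutamate receptor genes was 94.5 among genes with a mean of at least 5 FPKM. Presynaptic genes had a median of 0.18, with 18 of 22 intervals above 1 and Pclo, an active zone scaffold, at 0.53. Postsynaptic density genes had a median of 0.13 (percentile 99.55), with 12 of 24 intervals above 1 and Baiap2 at 0.46.

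Pan-neuronal markers had a median of 0.23 over 14 genes (percentile 100), with 10 intervals above 1 and 1 below. The neurofilament gene Nefm was at 170 FPKM against 120 FPKM and the dendritic protein gene Map2 at 209 FPKM against 159 FPKM. Axon growth and guidance genes had a median of 0.14 over 29 genes, with 19 intervals above 1 and 3 below, and Nfasc and Map1b at 0.60 and 0.40. This median was 0.09 after the length trend was removed. Excitatory cortical neuron markers had a median of 0.15 over 16 genes (percentile 99.6), with the vesicular glutamate transporter Slc17a7 at 0.64. Inhibitory neuron markers had a median of 0.13 over 16 genes (percentile 98.6, or 95.8 at a mean of at least 5 FPKM), with Dlx6 at 0.38 and Gad2 at 0.29. Longer genes had higher ratios across the table, with medians of -0.08 in the shortest and 0.11 in the longest of 10 length bins (Spearman rho 0.20 across genes).

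Immediate early genes, which neuronal activity induces, had the highest list median, 0.44 over 15 measured genes (percentile 100). Intervals lay above 1 for 12 members and below 1 for 1, Klf4 at -0.47. Fosb was at 0.87, Npas4 at 0.78, Nr4a1 at 0.75 and Junb at 0.58. Arc, Egr2, Egr3 and Egr4 fell below the filter, with intervals that include 1 and Arc at -0.29. These and Klf4 were chosen after their values were seen. Neuronal activity itself was not measured. In the same library pan-neuronal markers had a median of 0.23, cell cycle genes of -0.88 and progenitor markers of -0.30.

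For the injury named in the title, genes of cell death and stress are of interest. p53 target genes had a median of 0.19 over 19 genes (percentile 99.95), with 10 intervals above 1 and 0 below. The death receptor Fas was at 0.80 and Zmat3 at 0.75. Of the 19 genes, 5 were below 0. Among these was Cdkn1a, chosen after its value was seen, at -0.12 with a ratio of 0.918 (interval 0.792 to 1.06). Apoptosis promoting genes had a median of 0.05 over 22 genes (percentile 82.6), with 4 intervals above 1 and 4 below. Pmaip1, a BH3-only protein, was at 0.82 and Bok at -0.61. Bax, chosen after its value was seen, had a ratio of 0.998 (interval 0.886 to 1.13). Apoptosis restraining genes had a median of 0.00 over 15 genes (percentile 55.4), with 3 intervals on each side of 1. Bag3 was at 0.63, Mcl1 at -0.30 and Bcl2, chosen after its value was seen, at 0.00.

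Hypoxia and glycolysis genes had a median of -0.07 over 25 genes (percentile 13.8), with 3 intervals above 1 and 7 below. Aldoc was at 0.56, and Pgk1 and Pdk1 at -0.53 and -0.46. Oxidative stress and ferroptosis genes had a median of -0.11 over 26 genes (percentile 3.41, or 2.48 among protein-coding genes). Their median was -0.06 after rescaling to TPM or without the mitochondrial and top 20 genes. Hmox1 was at 0.49, Nqo1 at -0.64 and Prdx1 at -0.52. Integrated stress and unfolded protein response genes had a median of -0.01 over 23 genes (percentile 61.3), with 5 intervals above 1 and 5 below. Nupr1 was at -1.18 and Phgdh, of serine synthesis, at -1.10, while Dnajb9 was at 0.39. Heat shock genes had a median of -0.02 and a mean of 0.08 over 16 genes (percentile 58.9), with Hspb1 at 1.30 and Cryab at -0.77. After rescaling to TPM, the medians of 8 lists close to 0 changed sign, so no direction is given for them. They were the stress response, heat shock, m6A, mitochondrially encoded, astrocyte, extracellular matrix, autophagy and neurotrophin lists.

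All 28 measured cytosolic ribosomal protein genes had an interval below 1, with a median of -0.32 (percentile 0). Their median was -0.25 after the length trend was removed and -0.28 after rescaling to TPM. The percentile was also 0 among random lists matched on length. Rps6 was at 185 FPKM against 301 FPKM and Rps2 at 148 FPKM against 235 FPKM. Ribosomal protein genes have many near-identical pseudogenes, so the split of reads between copies is uncertain. The same library had medians of -0.88 for cell cycle genes, -0.30 for progenitor markers and 0.23 for pan-neuronal markers. Translation initiation and elongation factor genes had a median of -0.14 over 28 genes (percentile 0.75), with 21 intervals below 1 and 3 above, and Eef1b2 at -0.35. Eif4ebp1, which this list also holds and which encodes a repressor of initiation, was at -0.51. The median was -0.09 after rescaling to TPM or without the mitochondrial and top 20 genes. Nuclear-encoded oxidative phosphorylation genes had a median of -0.14 over 31 genes (percentile 0.67), with 20 intervals below 1 and 0 above. Their median was -0.09 under the same rescalings and -0.08 after the length trend was removed, and their percentile was 8.09 among random lists matched on length as well. Mitochondrially encoded genes had a median of -0.01 over 13 genes (percentile 83.1, or 97.6 with length matched).

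Genes of the m6A pathway, with Ythdf3 among them, had a median of -0.03 over 22 genes (percentile 44.1), with 6 intervals on each side of 1. The eraser Alkbh5 was at 0.52, the writer component Rbm15 at 0.37 and the reader Igf2bp3 at -0.33. Deadenylation and mRNA decay genes had a median of 0.06 over 26 genes (percentile 91.9), with Lsm1 at -0.36 and the exonuclease Xrn1 at 0.31.

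Interferon response genes had a median of -0.17 over 26 genes (percentile 0.14, or 3.22 with a median of -0.10 after a length trend was removed), with 9 intervals below 1 and 1 above. Gbp2 was at 24.9 FPKM against 47.0 FPKM. Mx2, chosen after its value was seen, was at 98.7 FPKM against 133 FPKM. Inflammation and NF-kB genes had a median of -0.07 over 23 genes (percentile 13.2), with 10 intervals below 1 and 4 above, and the percentile was 0.08 among genes with a mean of at least 5 FPKM. The interleukin genes Il1b and Il1a were at -0.82 and -0.79, and the complement gene C3 at 0.65. Microglia markers, with a median of -0.38, were lower in the same library as the interferon response list.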

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

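The removal of a length trend, the thinning to equal depth, the minimum of 20 reads and the lists matched on length were chosen after the data were seen. Counts of 2-fold genes depended on the treatment of low rows. Against 93 higher and 118 lower genes, a pseudocount of 1 FPKM gave 55 higher, no filter 249 higher and 231 lower, a mean of at least 5 FPKM 16 and 51, protein-coding genes only 26 and 69, at least 20 reads 37 and 76, and a 1.5-fold rule 317 and 520. The filters on a mean of 5 FPKM, on protein-coding genes and on 20 reads leave each ratio unchanged. All their calls are among the main calls, so the lower counts come from rows that were removed. With TPM, median centring, rescaling without the top genes, length removal and thinning the counts were 87 to 126 higher and 105 to 136 lower, and a pseudocount of 0.1 FPKM gave 125 and 170. Ythdf3 ranged from -0.36 to -0.47 and Wwtr1 from -0.87 to -1.05 over the alternatives, past 2-fold only with a pseudocount of 0.1 FPKM. Lists called above numbered 8 to 12 and lists below 9 to 11. The alternatives gave 1316 values of 188 genes, those the rule takes and some of those chosen later. Of these values 48 moved by more than the counting error of the ratio, and 0 of the genes 2-fold apart changed sign. The latter was nearly fixed beforehand. A pseudocount cannot change a sign, and the shift of log2 ratios on rescaling, about 0.05, and the length trend are small beside 2-fold. Of 477 list percentiles, 14 crossed a limit. Those not given with the lists were extracellular matrix at 1.65, inflammation at 0.72 and mitochondrially encoded genes at 98.15 after length removal, and oxidative phosphorylation at 4.38 with it. Median centring shifts all genes alike and cannot change a percentile, and rescaling without the top genes is nearly such a shift. Part of the 477 values was therefore fixed beforehand, and their number does not measure how stable the lists are. The planned correction for length and GC content together was not run. No paired analysis was possible because each group has 1 library and no test was run. Low read numbers limit these counts, with 56 of the 93 higher genes under 20 reads and 55 shorter than 200 bases.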

Other observations

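Several further lists lay between the limits. Extracellular matrix genes had a median log2 ratio of -0.04 over 25 genes (percentile 35.5), with 9 intervals above 1 and 11 below. Postn was at 0.576 FPKM in siYthdf3 and 1.71 FPKM in siNC, and the laminin gene Lama4 was higher at 0.71. Cholesterol synthesis genes had a median of 0.03 over 23 genes (percentile 80.9), with Stard4 at 0.49 and Cyp51 at -0.33. Autophagy and lysosome genes had a median of 0.00 over 24 genes (percentile 63.6), with Ctsz at -0.41. Neurotrophin and growth factor genes had a median of -0.02 over 11 genes (percentile 40.0), with Igf1r at 0.42. Of endothelial markers 1 was measured, Abcb1a at 0.35. Of choroid plexus and ependymal markers 3 were, with Foxj1 at -0.84, Rarres2 at -0.50 and Kcne2 at -0.19. Of 13 red blood cell markers 7 were found, without Hba-a1 and the beta globin genes, and 0 of these reached a mean of 1 FPKM, which leaves blood largely unexamined.

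The tests of the length bias in the cell cycle and progenitor lists, of the astrocyte list against each of them, of Wwtr1 and of Npvf were chosen after the result was seen. Those of depth and of length in the neuronal lists were set down before their results.

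Cell cycle and progenitor genes were lower and neuronal genes higher in siYthdf3, and gene length bias does not account for this alone, since 2 of 2 lower lists and 9 of 9 neuronal lists kept their calls among random lists matched on length and expression. With siYthdf3 reads thinned to the siNC depth, the cell cycle median was -0.90. FPKM is already scaled by depth, and thinning keeps the expected ratio of genes with many reads. This result was therefore nearly fixed beforehand, and no conclusion about depth is drawn from it. Fewer non-neuronal cells of every type would lower astrocyte markers alike. Their median was -0.02 with a lower quartile of -0.37, above the cell cycle upper quartile of -0.81, so this list did not fall as the cell cycle list did. It split, with 6 members above 0 and 6 below, among them Gfap at 1.04 and Gja1 at -0.68. The list therefore does not measure the number of astrocytes, and fewer non-neuronal cells stay open. For the progenitor markers they stay open too, since the astrocyte quartiles of -0.37 and 0.58 overlap theirs of -0.53 and -0.01. The oligodendrocyte, microglia and pericyte lists were lower at -0.35, -0.38 and -0.22, each with 2 members above 0. Fewer dividing progenitors after the knockdown, and a difference between the 2 samples unrelated to it, may each give the pattern, and neither was tested.

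Wwtr1 was lower in siYthdf3, and the upper bound of its ratio, 0.55, argues against counting error. Fewer dividing and progenitor cells stay open, for the lower YAP/TAZ target list as well. Of the measured cell cycle and progenitor genes 28.9%, 11 of 38, were at or below its log2 ratio, but this follows from the lower cell cycle list and does not show which cells express Wwtr1. An effect of Ythdf3 on Wwtr1 within cells stays open too, as does an off-target effect of the small interfering RNA. None of these was tested further.

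Npvf had the lowest ratio among the named genes, for which it was picked, and the upper bound of 0.089 argues against counting error as far as reads are separate molecules. Hypothalamic tissue in the siNC sample may bring Npvf, but of 13 other hypothalamic genes, listed after Npvf was seen, the most abundant in siNC was Pomc at 0.761 FPKM, far below the 23.7 FPKM of Npvf. Their sum was 2.03 FPKM in siNC and 1.70 FPKM in siYthdf3. An effect of the knockdown itself cannot be tested with 1 library per group.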
